A study of Mus musculus with 24 samples.

How the data were processed

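Chromatin of sorted mammary basal cells from C57BL/6 female mice was sheared to 200 to 400 bp and precipitated with antibodies against H3K4me3 or H3K27me3, per the labels' protocols. The labels list 24 samples, made of 16 immunoprecipitated libraries and 8 input samples; the inputs were not analysed here, so no value is relative to input. For each of the 16 libraries the authors deposited a raw read count for each of 27080 Entrez genes, without normalization. The counts were made with featureCounts on the mouse genome build mm10, per the submitters' processing notes. The aligner, the software versions, the gene annotation and the region counted for each gene are not given in the sources used here.

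The counts bear on that last point. Neighbouring genes with starts less than 1 kb apart were paired where the higher mean count was at least 30, for each mark separately. The H3K4me3 counts of 1671 such pairs had a median ratio of 1.01, and 82.5% of pairs lay within 10% of each other. By contrast, the H3K27me3 counts of 1152 such pairs had a median ratio of 4.02. Spearman's rho between gene length and mean count across genes was 0.34 for H3K4me3 and 0.8 for H3K27me3. H3K4me3 values are therefore read as counts around a gene start, which genes with a common promoter share, and H3K27me3 values as counts that grow with the length of the gene. Reads of overlapping genes cannot be told apart. Of the 58 genes that the naming rule took, 7 share a promoter within 2 kb with another gene (such as Tbx2 with 2610027K06Rik, Ptprt with 9430021M05Rik and Lrfn5 with Gm20063) and 17 overlap another gene (such as Pde3a, Filip1l, Itga1 and Plin4).

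Gene symbols and coordinates came from a RefSeq gene table of GRCm38.p6, the assembly that mm10 denotes, which matched 25189 of the 27080 Entrez identifiers and left 1891 without a symbol. Each mark was fitted on its own 8 libraries with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the subpopulation, which left 19009 genes for H3K4me3 and 22099 for H3K27me3, and TMM factors scaled the libraries. The model had a mean for each subpopulation and was tested with the robust quasi-likelihood F test, with Benjamini-Hochberg adjustment over the genes of a mark and comparison. A gene passed at an adjusted p under 0.05. With 4 residual degrees of freedom the fits leaned on the common spread, which was a biological coefficient of variation of 16% for H3K4me3 and 16.8% for H3K27me3. Total counts ran from 1472251 to 4740371 per library for H3K4me3 and from 2639862 to 6972189 for H3K27me3. CPM values are scaled with the TMM factors, and standard errors of a log2 fold change were obtained from its F statistic. The spread between libraries and counting error both set the precision, and counting error weighs more at genes with low counts.

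The comparisons were Tspan8hi minus Tspan8- averaged over both Lgr5 states, Lgr5+ minus Lgr5- averaged over both Tspan8 states (4 libraries against 4 in each), their interaction, and Lgr5+Tspan8hi against each other subpopulation (2 against 2). The 20 gene lists were basal and myoepithelial, luminal progenitor, hormone-sensing luminal, pan-luminal, fibroblast, pericyte, endothelial, immune, adipocyte, Schwann and neural, epidermal keratinocyte, Wnt pathway, Notch pathway, TGF-beta and BMP pathway, proliferation, quiescence and cyclin-dependent kinase inhibitor, Hox cluster, developmental transcription factor, ribosomal protein and olfactory receptor genes. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a mark and comparison. None of the camera calls held with an estimated correlation. The groups, tests, lists, comparisons, first set of other settings and the rule for naming genes were fixed before the data were examined.

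Genes were named by that rule. Lgr5 and Tspan8 were always given. For each mark and averaged effect, the 8 largest changes upward and the 8 largest downward were taken among genes past the threshold whose 4 libraries on one side all lay above the 4 on the other, leaving out predicted genes, clones, small RNAs and olfactory receptors. From each list up to 4 members past the threshold were taken by adjusted p. For the interaction and the comparisons of Lgr5+Tspan8hi up to 4 higher and 4 lower genes were taken by size, or the 4 smallest p where fewer passed. Across marks up to 8 genes past the threshold in opposite directions were taken. Members of lists that did not pass singly, and the genes said to be so, were picked after their values were seen. A few genes that the rule took are not reported here.

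The first set of other settings held DESeq2 1.42.0 (Wald test), limma-voom, RLE size factors, library totals alone, loess offsets of each library against mean abundance, no filter on low counts, a mean of at least 5 CPM, the replicate number as a block, each library left out in turn, and for the lists fry and an estimated correlation. Added after seeing the data were limma-voom with library quality weights, loess offsets of H3K27me3 libraries against reads per kb of gene, promoters within 2 kb counted as 1, and the list tests and the comparison of marks for Lgr5+Tspan8hi against Lgr5-Tspan8-. Random lists for the comparison of marks were drawn 10000 times. Library measures and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.

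The fit was tested on simulated data with the real means, library sizes and spread and 100 genes changed at each of 2 sizes. In the H3K4me3 Tspan8 comparison it recovered 76% of 2-fold and 37% of 1.5-fold changes, and in that of Lgr5+Tspan8hi with Lgr5-Tspan8- 52% and 8%. For H3K27me3 the shares were 52% and 22%, and 37% and 7%. Changes of 1.5-fold were thus mostly missed at this depth and number of libraries. Unchanged genes made up 9 of 122 and 1 of 61 calls for H3K4me3 and 4 of 78 and 10 of 54 for H3K27me3, in the same order. Over 20 such simulations their mean share of the calls was 6.11% and 5.4% for H3K4me3 and 4.8% and 4.4% for H3K27me3, and it reached 14.9%, 12.3%, 10% and 15% in single simulations. Simulated genes were drawn independently of each other, without differences that a library shares over many genes, such as those in effective depth. These shares therefore do not give the error rate of the real calls. Y-linked genes were checked as a sign of misassigned reads, with sums of 0 to 3 counts per H3K4me3 library and 22 to 88 per H3K27me3 library over 109 genes.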

Results

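Basal cells of the mouse mammary gland form the outer epithelial layer, which holds the contractile myoepithelial cells and cells able to rebuild the gland after transplantation. In this series such cells from C57BL/6 females were sorted into 4 subpopulations by Lgr5, a receptor for R-spondins that strengthens Wnt signalling, and Tspan8, a tetraspanin of the cell membrane. The subpopulations were Lgr5+Tspan8hi (double-positive), Lgr5+Tspan8-, Lgr5-Tspan8hi and Lgr5-Tspan8- (double-negative). The title places the work in a search for mammary stem cells that divide rarely, sit in a restricted part of the gland and respond to hormones. The question put to the chromatin was how the histone marks of these cells differ with Lgr5 and with Tspan8. Chromatin immunoprecipitation followed by sequencing measured H3K4me3, a mark of active and poised promoters, and H3K27me3, the repressive mark laid down by Polycomb complexes. Each mark had 2 libraries in each of the 4 subpopulations, which made 16 libraries. The 8 input libraries were not analysed here.

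Total counts in the H3K4me3 libraries were 2356047 and 3260828 in Lgr5+Tspan8hi, 2797501 and 1472251 in Lgr5+Tspan8-, 2241266 and 2556928 in Lgr5-Tspan8hi, and 1713771 and 4740371 in Lgr5-Tspan8- cells. In the H3K27me3 libraries they were 5888558 and 5336563, 5148698 and 5207820, 2639862 and 6300093, and 4338218 and 6972189, in the same order. Replicate libraries of every group differed by more than sampling noise, with a chi-square per degree of freedom of 2.9 to 4.89 for H3K4me3 and 3.4 to 5.43 for H3K27me3. The labels do not say whether replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical. Libraries also differed in how many genes had no count at a given total. Expressed as an effective depth, which is the percent of the total count at which independent reads would leave as many genes at 0, the H3K4me3 libraries of Tspan8hi cells reached 34.4% ± 7.39 (SD, n = 4) and those of Tspan8- cells 53.6% ± 6.91 (SD, n = 4; exact two-sided permutation p = 0.0286, the smallest that 70 arrangements allow). For H3K27me3 the values were 42.5% ± 9.3 and 62.4% ± 3.43 (SD, n = 4 each; exact two-sided permutation p = 0.0286). Lgr5+ and Lgr5- libraries did not differ detectably in effective depth (exact two-sided permutation p = 0.914 for H3K4me3 and 0.886 for H3K27me3, n = 4 each).

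**Figure D1:**
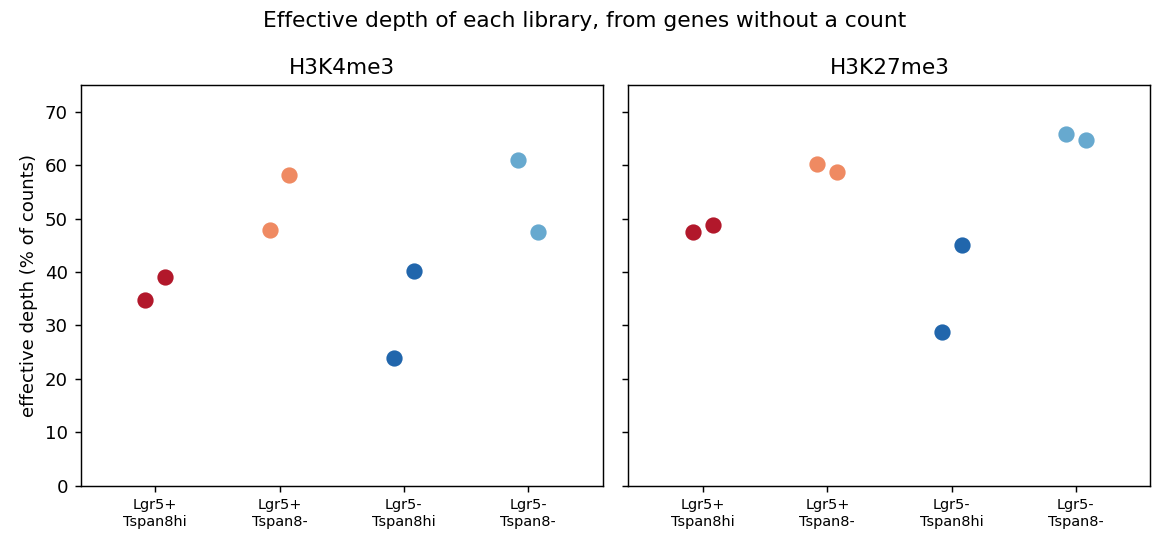
Effective depth of each of the 16 libraries, in percent of its total count, by subpopulation and histone mark; each point is a library. For H3K4me3 the 4 Tspan8hi libraries lay between 23.9% and 40.1% and the 4 Tspan8- libraries between 47.5% and 60.9%, and for H3K27me3 between 28.7% and 48.7% against 58.8% and 65.9%.

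The sorting genes checked the labels. At Tspan8 (chromosome 10, 115816817 to 115849893, plus strand, GRCm38), H3K4me3 was 80.7 ± 8.89 CPM (counts scaled to the library total; SD, n = 4) in Tspan8hi and 25.2 ± 4.17 CPM in Tspan8- libraries. This was a 3.21-fold difference. It had a log2 fold change of 1.68 ± 0.18 (SE) and an edgeR adjusted p of 3.25e-11. H3K27me3 at Tspan8 ran the other way, at 12.5 ± 2.24 against 21.4 ± 5.46 CPM, but did not pass over all genes (log2 fold change -0.72 ± 0.20, edgeR adjusted p = 0.104), although 3 of 17 alternatives took it past the threshold. At Lgr5 (chromosome 10, 115450314 to 115587780, minus strand), H3K4me3 was 88.0 ± 17.7 CPM in Lgr5+ and 70.0 ± 12.5 CPM in Lgr5- libraries, a log2 difference of 0.32 ± 0.14 that did not pass (edgeR adjusted p = 0.961). H3K27me3 at Lgr5 was 74.9 ± 24.8 CPM in Lgr5+ and 124 ± 28.1 CPM in Lgr5- libraries, with a log2 fold change of -0.72 ± 0.14 just short of the threshold (edgeR adjusted p = 0.0536). Of 18 alternatives 10 took it past the threshold, with adjusted p from 0.00049 to 0.511 and log2 fold changes from -0.96 to -0.54 over all 18. Neither gene passed in the comparison made on the other one. Lgr5 H3K4me3 differed by -0.02 and H3K27me3 by 0.01 with Tspan8, and Tspan8 H3K4me3 by 0.07 and H3K27me3 by -0.24 with Lgr5, in log2 units (edgeR adjusted p from 0.859 to 1.0).

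**Figure D2:**
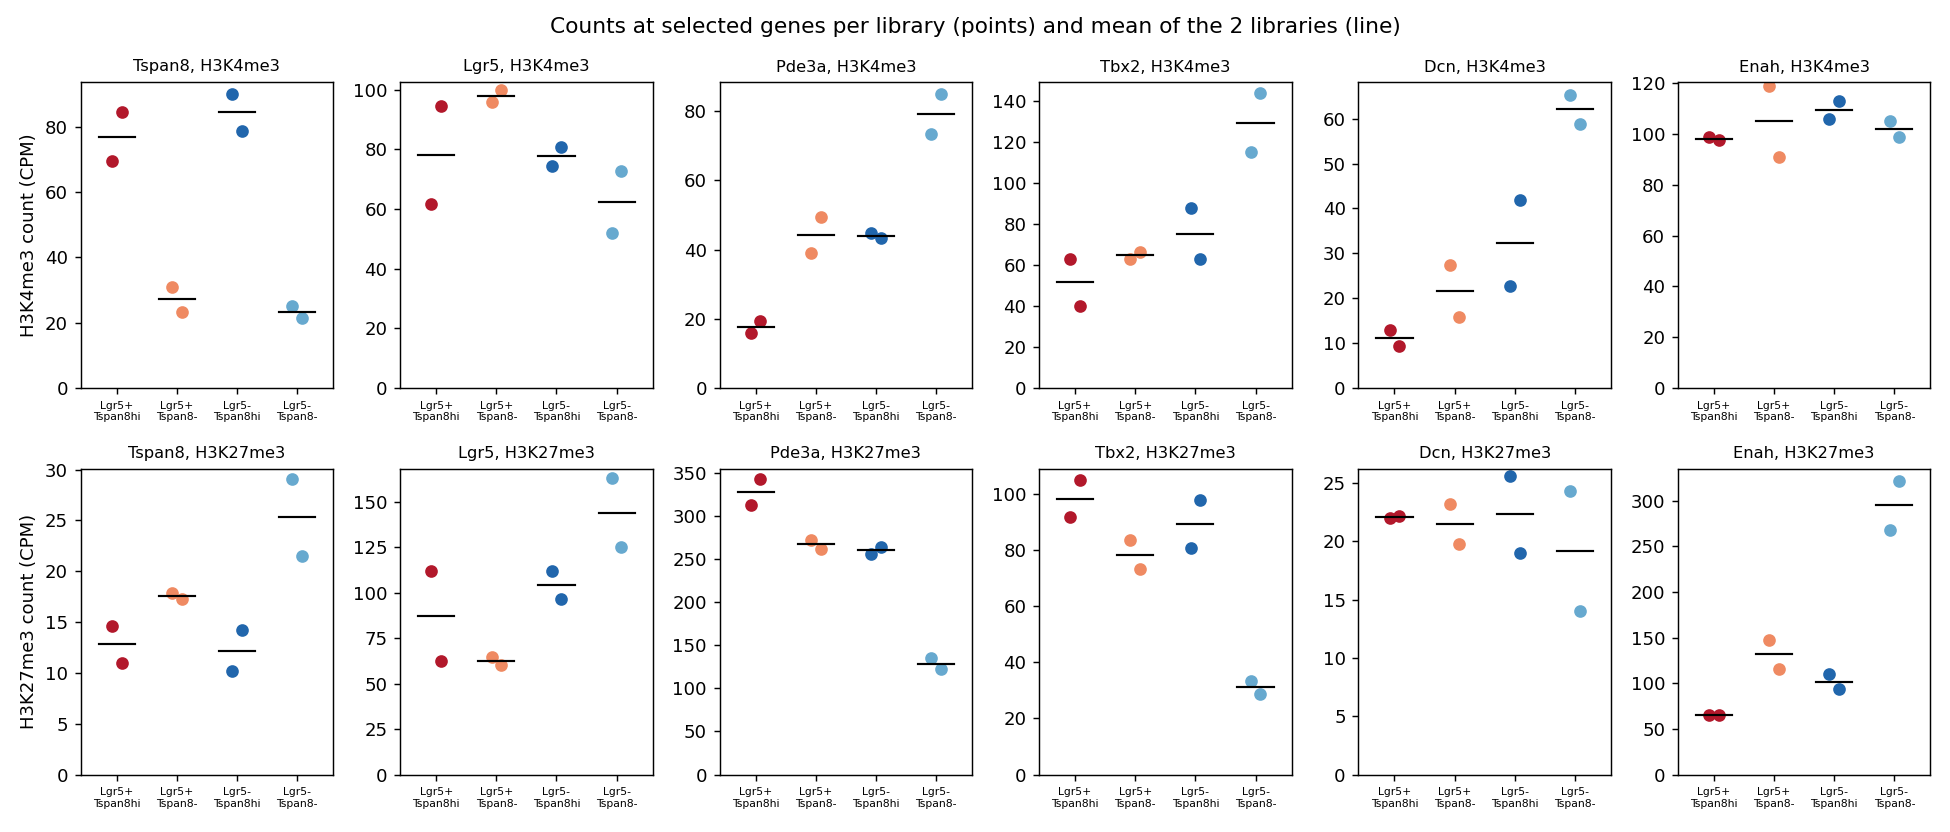
CPM of 6 genes in each library of H3K4me3 and H3K27me3 by subpopulation; each point is a library and each line the mean of 2 libraries. H3K4me3 at Tspan8 followed Tspan8 (76.9 CPM in double-positive and 23.2 CPM in double-negative cells), Pde3a fell from 79.2 to 17.6 CPM in H3K4me3 while it rose from 128 to 328 CPM in H3K27me3 from double-negative to double-positive cells, and H3K27me3 at Enah was 65.4 CPM in double-positive and 295 CPM in double-negative cells.

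The Tspan8 comparison asked what goes with a high level of Tspan8 over both Lgr5 states. Besides Tspan8, promoters with H3K4me3 past the threshold were all lower in Tspan8hi libraries. They included Tmem215 (chromosome 4, 40472180 to 40475653), at 7.7 ± 3.52 against 26.4 ± 11.9 CPM, and Hs3st4, a heparan sulfate sulfotransferase (chromosome 7, 123982366 to 124398989), at 6.93 ± 3.0 against 21.7 ± 9.28 CPM (SD, n = 4 each). Their log2 fold changes were -1.71 ± 0.33 and -1.70 ± 0.35 (edgeR adjusted p = 0.00548 and 0.0137). Asb2, a ubiquitin ligase subunit that targets filamins, fell by 1.27 ± 0.24 (SE) on the log2 scale, from 40.7 ± 8.12 to 16.6 ± 2.2 CPM (edgeR adjusted p = 0.00519). Filip1l, which encodes a protein related to the filamin-interacting FILIP1, stood at 41.9 ± 4.29 against 74.1 ± 3.72 CPM, and Fbxl22, an F-box protein, at 29.2 ± 4.47 against 54.3 ± 9.76 CPM (log2 fold change -0.82 and -0.89, edgeR adjusted p = 0.00992 and 0.0261). Lrfn5, a synaptic adhesion gene, was lower by a log2 fold change of -1.22 ± 0.25 (edgeR adjusted p = 0.00992). Pde3a, a cyclic nucleotide phosphodiesterase (chromosome 6, 141249269 to 141506862), had a log2 fold change of -1.08 ± 0.19 with overlapping libraries of the 2 sides (edgeR adjusted p = 0.00118).

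In all, H3K4me3 was higher at 1 and lower at 8 of 19009 genes, or 1 and 7 promoters when gene starts within 2 kb were taken as 1. A total of 1122 genes had an unadjusted p under 0.05, and DESeq2 called 9 and limma-voom 13 genes. Effective depth was lower in all 4 Tspan8hi libraries. The count was 14 without Lgr5+Tspan8- replicate 1, 1 without Lgr5+Tspan8- replicate 2 or Lgr5-Tspan8- replicate 2, 2 without Lgr5+Tspan8hi replicate 2 and 64 without Lgr5-Tspan8hi replicate 2. Of these 8 named genes past the threshold, Tspan8 kept its call under every alternative tried, and leaving out Lgr5+Tspan8- replicate 2 or Lgr5-Tspan8- replicate 2 ended 7 calls, Lgr5+Tspan8hi replicate 2 ended 6, Lgr5-Tspan8hi replicate 1 ended 4, Lgr5+Tspan8hi replicate 1 or Lgr5-Tspan8- replicate 1 ended 2, and Lgr5+Tspan8- replicate 1 ended 1. Limma-voom ended 1 as well.

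Of the 20 gene lists, H3K4me3 at pan-luminal genes was higher in Tspan8hi libraries, with 11 of 12 members above 0 and a median log2 fold change of 0.14 (camera adjusted p = 0.00944; adjusted p = 0.508 with an estimated correlation). Elf3, an epithelial transcription factor, had a value of 0.58, the claudin gene Cldn7 0.45 and the keratin gene Krt19 0.29, and no member passed the test for single genes. Fibroblast markers were lower, with 9 of 12 members below 0 and a median of -0.25, which was -0.11 with loess offsets (camera adjusted p = 0.00944 and 0.0244; adjusted p = 0.565 with an estimated correlation). Of these, 2 were lower adjusted over the list alone. Dcn, the matrix proteoglycan decorin, stood at -0.97 (edgeR adjusted p = 0.123) and the mesenchymal factor Prrx1 at -0.49. Olfactory receptor genes, whose products act in the nose, had a median of -0.22, with 54 of 91 members below 0 (camera adjusted p = 0.0043; adjusted p = 0.584 with an estimated correlation), and with loess offsets their median turned to 0.17 (camera adjusted p = 0.671). The other 17 lists did not pass (camera adjusted p from 0.176 to 0.963). The Tspan8hi libraries behind these groups also had the lower effective depth. The pan-luminal call ended without Lgr5+Tspan8- replicate 2, Lgr5+Tspan8hi replicate 1 or Lgr5-Tspan8hi replicate 1 (camera adjusted p = 0.101, 0.0534 and 0.0669). The fibroblast call ended without Lgr5-Tspan8hi replicate 1 (0.276) or with no filter (0.0661), and the olfactory call without Lgr5+Tspan8- replicate 2 (0.433) or with a mean of at least 5 CPM (0.063), in camera with the preset correlation.

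The Lgr5 comparison asked the same of Lgr5 over both Tspan8 states. H3K4me3 at Dcn (chromosome 10, 97479500 to 97518163) was 16.3 ± 7.79 CPM in Lgr5+ and 47.2 ± 19.1 CPM in Lgr5- libraries (SD, n = 4 each). This was a 2.86-fold lower level, with a log2 fold change of -1.52 ± 0.24 (edgeR adjusted p = 0.000145), and 3 of the 4 Lgr5+ libraries lay below all Lgr5- libraries. Pde3a was at 30.9 ± 16 against 61.6 ± 20.8 CPM (log2 fold change -1.09 ± 0.19, edgeR adjusted p = 0.000877). Tbx2, a T-box transcription factor of the mammary line (chromosome 11, 85832615 to 85841948), was at 58.1 ± 12.2 against 103 ± 35.2 CPM (-0.79 ± 0.15, edgeR adjusted p = 0.00322), with overlapping libraries and 130 CPM in Lgr5-Tspan8- against 75.3 CPM in Lgr5-Tspan8hi cells. Ptprt, a receptor tyrosine phosphatase (chromosome 2, 161521988 to 162661147), was at 37.5 ± 12.9 against 64.5 ± 12 CPM (-0.84 ± 0.18, edgeR adjusted p = 0.0336). The other genes past the threshold, named after their values were seen, were Cntn2 and Tbx3os2, higher in Lgr5+ libraries, and 2610027K06Rik and 9430021M05Rik, which share promoters with Tbx2 and Ptprt and were lower. H3K4me3 was thus higher at 2 and lower at 6 genes (2 and 4 promoters), 947 genes had an unadjusted p under 0.05, and DESeq2 called 5 and limma-voom 11. The count fell to 1 without Lgr5-Tspan8- replicate 2, to 2 without Lgr5+Tspan8hi replicate 2 or Lgr5-Tspan8hi replicate 1, and to 5 without Lgr5+Tspan8hi replicate 1, and without Lgr5+Tspan8- replicate 1 it was 4 higher and 2 lower. Dcn kept its call under every alternative, and of the 4 named calls 3 ended without Lgr5-Tspan8- replicate 2, 2 without Lgr5+Tspan8- replicate 1, Lgr5+Tspan8hi replicate 2 or Lgr5-Tspan8hi replicate 1, and 1 without Lgr5+Tspan8hi replicate 1 or with DESeq2.

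Developmental transcription factor genes under Polycomb control had lower H3K4me3 in Lgr5+ libraries, with 21 of 30 members below 0 and a median log2 fold change of -0.21 (camera adjusted p = 0.00302; adjusted p = 0.584 with an estimated correlation). Neurog2 stood at -0.37, and no member passed singly, over all genes or adjusted over the list alone. The call ended without Lgr5+Tspan8- replicate 1 (camera adjusted p = 0.11). Of the fibroblast markers, Dcn passed over all genes and as the 1 lower member adjusted over the list alone, while the list had a median of -0.08 (camera adjusted p = 0.489). The 19 lists that did not pass had camera adjusted p from 0.489 to 0.998.

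**Figure D3:**
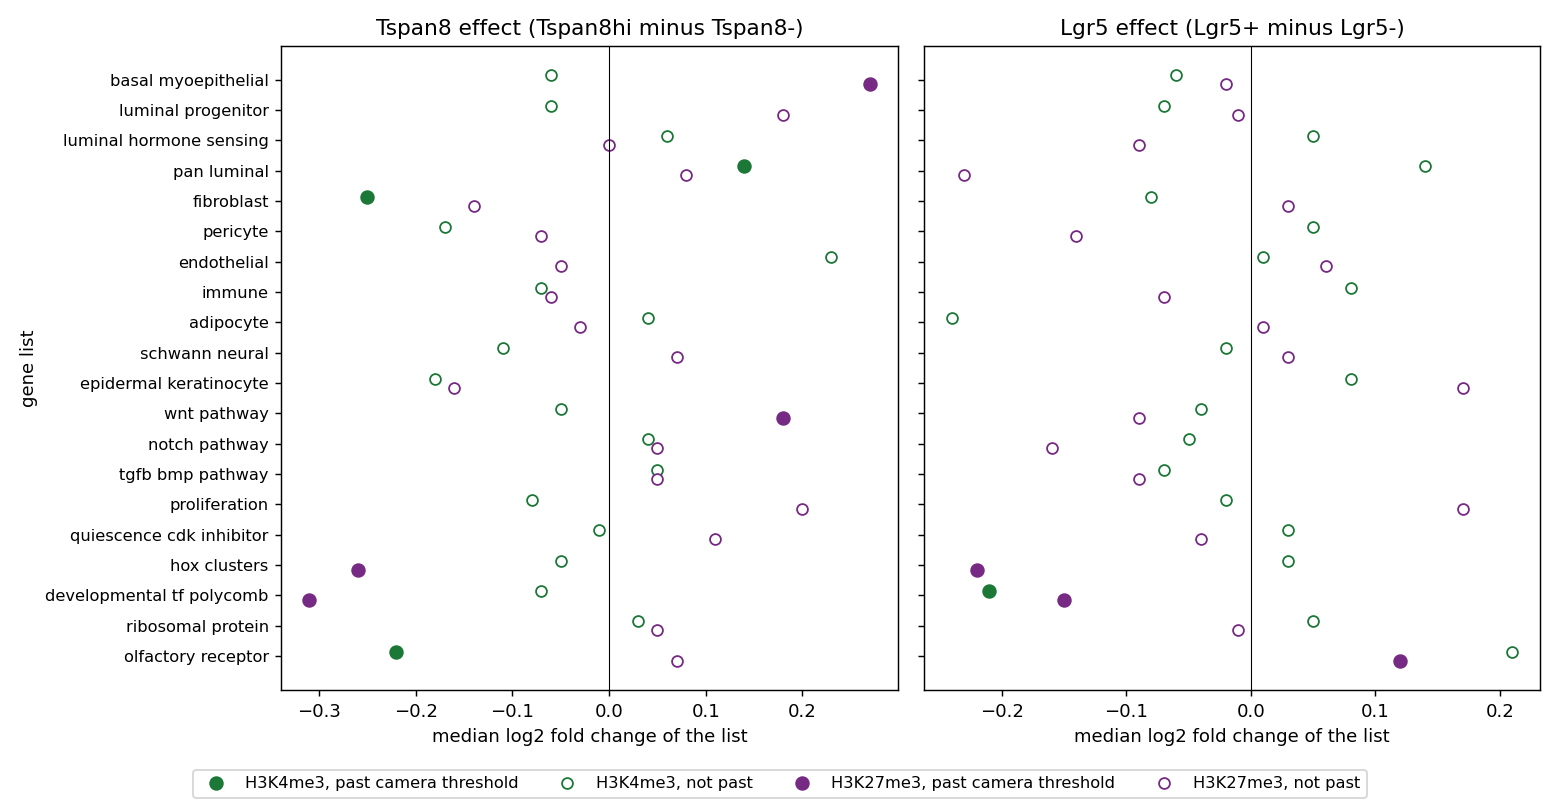
Median log2 fold change of the 20 gene lists in the Tspan8 comparison (left) and the Lgr5 comparison (right), for H3K4me3 (green) and H3K27me3 (purple); each point is a list and filled points passed camera with the preset correlation. H3K27me3 at Hox genes lay at -0.26 and -0.22 and at developmental transcription factor genes at -0.31 and -0.15 (with offsets against reads per kb -0.07 and -0.01, and -0.07 and 0.03, none passing, camera adjusted p from 0.218 to 0.659), and H3K4me3 at olfactory receptor genes at -0.22 in the Tspan8 comparison (0.17 with loess offsets).

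H3K27me3 differed at more genes with Tspan8. Enah, which promotes actin filament elongation (chromosome 1, 181896384 to 182027556), was lower in Tspan8hi libraries, at 83.6 ± 22.2 against 214 ± 97.6 CPM (SD, n = 4 each), with a log2 fold change of -1.28 ± 0.11 (edgeR adjusted p = 2.79e-07). The tight junction gene Ocln (chromosome 13, 100496504 to 100552718) was at 50.9 ± 10.2 against 98.0 ± 36.7 CPM, and Cecr2, a bromodomain protein of chromatin remodelling complexes (chromosome 6, 120666314 to 120771191), at 181 ± 19.1 against 308 ± 30.7 CPM. Their log2 fold changes were -0.88 ± 0.12 and -0.77 ± 0.09 (edgeR adjusted p = 0.00036 and 0.000128). Pparg, the main regulator of fat cell formation and a member of the adipocyte list, was at 258 ± 23.5 against 362 ± 18.6 CPM (-0.49 ± 0.09, edgeR adjusted p = 0.00653). The chemokine gene Cxcl9 (-0.89), the metalloproteinase gene Adamts6 (-0.75), Lox, which crosslinks collagen and elastin (-0.75), the X-linked Tbc1d25 (-0.71) and Fsd2 (-0.68) were also lower (edgeR adjusted p from 0.00222 to 0.0487). Higher in Tspan8hi libraries were Fzd10, a Wnt receptor, at 18.3 ± 4.57 against 7.83 ± 2.2 CPM (1.23 ± 0.25, edgeR adjusted p = 0.0223). So were the neurotrophin gene Ntf3 at 90.4 ± 9.27 against 53.8 ± 10.8 CPM (0.76 ± 0.13, edgeR adjusted p = 0.00437) and the collagen-binding integrin Itga1 at 80.6 ± 10.1 against 48.7 ± 7.81 CPM (0.72 ± 0.13, edgeR adjusted p = 0.00768). Pde3a reached 294 ± 41.3 against 198 ± 80.1 CPM (0.66 ± 0.09, edgeR adjusted p = 0.000439). Asb2 (0.81), Diras2 (0.74), Hs3st3a1 (0.69) and Mrvi1 (0.67) passed in the same direction (edgeR adjusted p from 0.00768 to 0.0487).

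H3K27me3 was higher at 21 and lower at 53 of 22099 genes, so that 71.6% of the differences were lower. Loess offsets gave 49 higher and 33 lower, and library totals alone 36 and 28. Of the lower genes 8 were X-linked. At an unadjusted p under 0.05 there were 2843 genes, and DESeq2 called 476 and limma-voom 294. Effective depth was lower in all 4 Tspan8hi libraries. The count was 6 and 10 without Lgr5+Tspan8- replicate 1 and 2, 17 and 18 without Lgr5+Tspan8hi replicate 1 and 2, 1091 and 26 without Lgr5-Tspan8- replicate 1 and 2, and 40 and 583 without Lgr5-Tspan8hi replicate 1 and 2. Enah, Ocln, Cecr2 and Pde3a kept their calls under every alternative. Of the 18 genes past the threshold that the naming rule took, 14 lost the call without Lgr5+Tspan8- replicate 1 and 13 without replicate 2, 10 and 12 without Lgr5+Tspan8hi replicate 1 and 2, 10 without Lgr5-Tspan8- replicate 2 and 4 without Lgr5-Tspan8hi replicate 1. Offsets against reads per kb ended 3 of these calls, library totals 2 and RLE size factors 1, and DESeq2 gave no adjusted p for 6 of the genes. H3K4me3 did not differ detectably at Enah (104 ± 7.14 against 104 ± 11.9 CPM), Ocln, Cecr2, Pparg or Fzd10 (log2 fold change 0.00, 0.08, -0.09, 0.04 and -0.42, edgeR adjusted p from 0.488 to 0.998).

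Among the lists, H3K27me3 was lower in Tspan8hi libraries at Hox genes, which set positional identity, with 38 of 39 members below 0 and a median log2 fold change of -0.26 (camera adjusted p = 5.6e-09; adjusted p = 0.705 with an estimated correlation). No Hox gene passed over all genes and 9 passed as lower adjusted over the list alone; Hoxa3 stood at -0.39 and Hoxb7 at -0.59. All 30 developmental transcription factor genes were below 0, with a median of -0.31 and 17 lower adjusted over the list alone (camera adjusted p = 1.13e-12; adjusted p = 0.705 with an estimated correlation), including Evx1 at -0.57, Lhx9 at -0.38 and Pax3 at -0.35. Basal and myoepithelial genes were higher, with 17 of 20 above 0, a median of 0.27 and 1 higher adjusted over the list alone (camera adjusted p = 0.00357; adjusted p = 0.705 with an estimated correlation). The contractile genes Mylk (0.38), Myh11 (0.40) and Tagln (1.46) and the cytolinker gene Dst (0.29) belong to it. Wnt pathway genes were higher, with 14 of 20 above 0, a median of 0.18 and 1 higher adjusted over the list alone (camera adjusted p = 0.0473; adjusted p = 0.705 with an estimated correlation), including Wnt6 at 0.91, Wnt10a at 0.57 and Nkd1, a feedback inhibitor of Wnt signalling, at 0.47. The remaining 16 lists did not pass (camera adjusted p from 0.432 to 0.886), although Pparg did within the adipocyte list. The Tspan8hi libraries behind these groups also had the lower effective depth. With offsets against reads per kb of gene no list passed, the medians being -0.07 for Hox and developmental genes, 0.14 for basal and 0.12 for Wnt genes (camera adjusted p from 0.143 to 0.659). The basal call was also lost without 3 of the 8 libraries, Lgr5+Tspan8hi replicate 1, Lgr5-Tspan8- replicate 2 and Lgr5-Tspan8hi replicate 1 (camera adjusted p = 0.529, 0.427 and 0.132). The Wnt call was lost without 5 of the 8, these 3 (0.529, 0.506 and 0.132) and both Lgr5+Tspan8- libraries (0.0803 and 0.0792), and with a mean of at least 5 CPM (0.072).

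**Figure D4:**
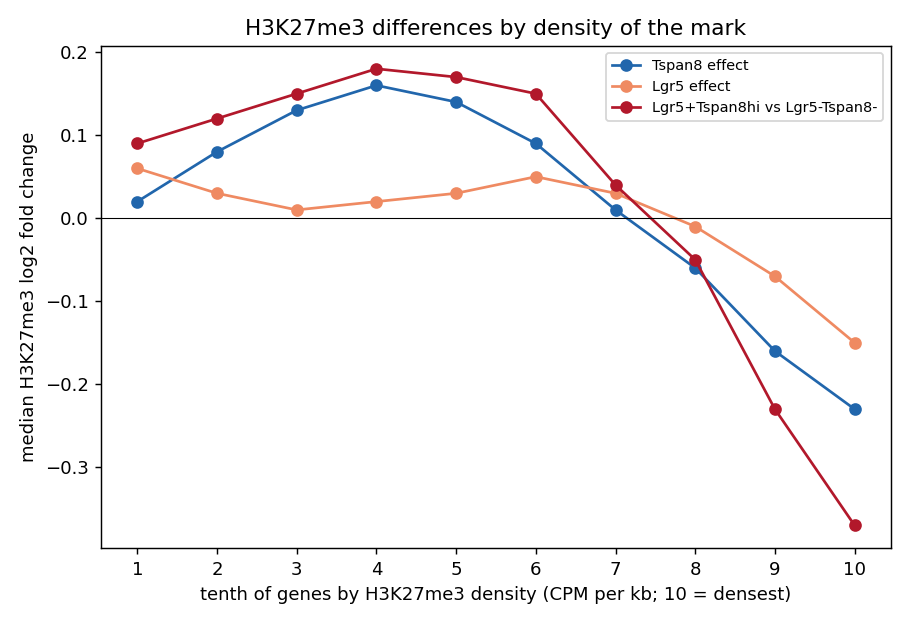
Median log2 fold change of H3K27me3 (vertical axis) in deciles of genes ordered by their mean CPM per kb of gene (horizontal axis), for 3 comparisons; each point is a decile. In the densest decile the medians were -0.23 for Tspan8, -0.15 for Lgr5 and -0.37 for double-positive against double-negative cells, and in the fourth decile 0.16 for Tspan8 and 0.18 for the last comparison.

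With Lgr5, H3K27me3 was higher in Lgr5+ libraries at 3 of the genes whose H3K4me3 was lower. Pde3a was at 297 ± 37.7 against 194 ± 76.2 CPM (log2 fold change 0.69 ± 0.09, edgeR adjusted p = 0.000423; SD, n = 4 each). Tbx2 was at 88.3 ± 13.4 against 60.2 ± 34.3 CPM (0.73 ± 0.12, edgeR adjusted p = 0.0113) and Ptprt at 1800 ± 62.1 against 1330 ± 255 CPM (0.46 ± 0.07, edgeR adjusted p = 0.00536). At Tbx2 the libraries of the 2 sides overlapped, since H3K27me3 was 98.3, 78.3 and 89.2 CPM in Lgr5+Tspan8hi, Lgr5+Tspan8- and Lgr5-Tspan8hi cells and 31.2 CPM in Lgr5-Tspan8- cells. Its interaction of -1.21 ± 0.24 did not pass (edgeR adjusted p = 0.159), although 5 of 18 alternatives took it past the threshold. Pde3a overlapped too, at 328, 267, 260 and 128 CPM in the same order. H3K27me3 was lower at Nfatc1, a calcium-regulated transcription factor, at 55.9 ± 9.85 against 89.6 ± 19.1 CPM (-0.68 ± 0.12, edgeR adjusted p = 0.0299), at the adhesion gene Cadm4 and at the adrenergic receptor gene Adra1d (both -0.74, edgeR adjusted p = 0.0478). Enah, Ocln and Gli2, named here after their values were seen, made up the 6 lower genes, beside 3 higher ones. There were 1589 genes with an unadjusted p under 0.05, and DESeq2 called 71 and limma-voom 47. The count was 2 without either Lgr5+Tspan8- library or Lgr5+Tspan8hi replicate 2, 112 without Lgr5-Tspan8- replicate 1 and 180 without Lgr5-Tspan8hi replicate 2, the last with 115 higher and 65 lower. Pde3a kept its call under every alternative. In all, 5 of the 6 named calls ended without either Lgr5+Tspan8- library or Lgr5+Tspan8hi replicate 2, 4 without Lgr5-Tspan8- replicate 2, 3 without Lgr5+Tspan8hi replicate 1 and 1 without Lgr5-Tspan8hi replicate 1 or with library totals alone.

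Hox genes had lower H3K27me3 in Lgr5+ libraries, with 34 of 39 below 0 and a median of -0.22, which was -0.01 with offsets against reads per kb (camera adjusted p = 1.34e-06 and 0.643; adjusted p = 0.603 with an estimated correlation). Developmental transcription factor genes had 28 of 30 below 0 and a median of -0.15, which turned to 0.03 with those offsets (camera adjusted p = 7.91e-05 and 0.643; adjusted p = 0.674 with an estimated correlation). Olfactory receptor genes were higher, with 377 of 640 above 0 and a median of 0.12 (camera adjusted p = 0.0189; adjusted p = 0.0841 with an estimated correlation), a call that ended with loess offsets (0.0817) or a mean of at least 5 CPM (0.144). No member of these lists passed over all genes or adjusted over the list alone. The other 17 lists had camera adjusted p from 0.176 to 0.957. Without Lgr5-Tspan8- replicate 2 all 3 calls ended (camera adjusted p = 0.0899 for Hox, 0.543 for developmental and 0.0572 for olfactory genes), as they did without Lgr5-Tspan8hi replicate 2 (0.0553, 0.0553 and 0.212). The developmental call also ended without Lgr5+Tspan8hi replicate 1 (0.101), and the olfactory call without Lgr5+Tspan8- replicate 1 or Lgr5+Tspan8hi replicate 2 (0.0733 and 0.0527).

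Whether the difference with Tspan8 depended on Lgr5 was tested as an interaction. For H3K27me3 it passed at Grik3, a kainate receptor subunit (chromosome 4, 125490259 to 125714173), with 1.88 ± 0.24 log2 units (edgeR adjusted p = 0.000717), and at Rimklb, a glutamate ligase (chromosome 6, 122447296 to 122487062), with 2.10 ± 0.34 (edgeR adjusted p = 0.0183). At both genes the difference, Tspan8hi minus Tspan8-, was more positive in Lgr5+ than in Lgr5- cells. The highest adjusted p without 1 library was 0.104 for Grik3 and 0.636 for Rimklb (edgeR), and DESeq2 gave no adjusted p for Rimklb. Across genes 1215 had an unadjusted p under 0.05, and DESeq2 called 12 and limma-voom 2. The count was 0 without either Lgr5+Tspan8- library, 1 without Lgr5+Tspan8hi replicate 1 or Lgr5-Tspan8- replicate 1, 5 without Lgr5+Tspan8hi replicate 2, 33 without Lgr5-Tspan8- replicate 2 and 110 without Lgr5-Tspan8hi replicate 2. For H3K4me3 edgeR called 0 genes and DESeq2 0, with 799 at an unadjusted p under 0.05, while limma-voom called 2. The count was 3 without Lgr5+Tspan8- replicate 1 and 7 without Lgr5-Tspan8hi replicate 2. Among the genes with the smallest p were Tmem200c (-1.38 ± 0.32), Il7 (-1.08) and Dmrta1 (2.93), none past the threshold (edgeR adjusted p from 0.626 to 1.0).

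Double-positive cells were then set against each other subpopulation, 2 libraries against 2. Against Lgr5+Tspan8- cells, H3K4me3 was higher at Tspan8, at 76.9 ± 10.7 against 27.1 ± 5.45 CPM (log2 fold change 1.48 ± 0.25, edgeR adjusted p = 0.0013), and at no other gene. There were 849 genes with an unadjusted p under 0.05, and DESeq2 called 1 and limma-voom 4, of which 3 were lower. The Tspan8 call ended without Lgr5+Tspan8- replicate 2 or Lgr5+Tspan8hi replicate 2, while 6 genes, 5 of them lower, passed without Lgr5+Tspan8- replicate 1 and 2 without either Lgr5-Tspan8hi library. Pde3a stood at -1.30 without passing (edgeR adjusted p = 0.13). H3K27me3 was lower at Enah, at 65.4 ± 0.121 against 132 ± 22.6 CPM (-1.01 ± 0.16, edgeR adjusted p = 0.0188), and at Cecr2, at 167 ± 7.37 against 291 ± 23.8 CPM (-0.80 ± 0.13, edgeR adjusted p = 0.022). These were the 2 genes past the threshold, of 1735 with an unadjusted p under 0.05, and both were lower. DESeq2 called 45 higher and 20 lower genes, limma-voom 22 and 9, offsets against reads per kb 7 and 7, loess offsets 9 and 2, and library totals alone 5 and 2. Of the genes with the smallest p, H3K27me3 stood higher without passing at Mylk (0.88), Adam12 (0.80), Hs3st3a1 (0.92) and Mef2c (0.81), each with an edgeR adjusted p of 0.0609, and 13, 12, 12 and 12 of 18 alternatives took them past the threshold. The calls at Enah and Cecr2 ended without any 1 of the 4 libraries compared, although 11 other genes, all higher, passed without Lgr5+Tspan8hi replicate 2. The count was 70 and 86 without Lgr5-Tspan8- replicate 1 and 2 and 40 and 38 without Lgr5-Tspan8hi replicate 1 and 2, of which 50, 67, 35 and 33 were higher.

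Against Lgr5-Tspan8hi cells 0 genes passed for either mark in edgeR, DESeq2 or limma-voom, with 1324 genes for H3K4me3 and 1595 for H3K27me3 at an unadjusted p under 0.05. The smallest p for H3K4me3 were at Pde3a (log2 fold change -1.31), Dcn (-1.56), Ptprt (-1.12) and Sox5 (-1.03), with edgeR adjusted p from 0.166 to 0.211, and for H3K27me3 at Gli2 (-0.59), Dmc1 (-0.77), Tmem215 (1.92) and Rimklb (1.01). Without Lgr5-Tspan8hi replicate 2, 51 genes passed for H3K4me3 and 323 for H3K27me3, and without replicate 1 of that group 1 gene passed for H3K4me3.

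With all libraries, double-positive and double-negative cells, which differ in both markers, showed the most genes past the threshold in each mark. Without Lgr5-Tspan8hi replicate 2 the Tspan8 comparison showed more in both marks. H3K4me3 at Dcn was 11.1 ± 2.45 CPM in double-positive and 62.1 ± 4.54 CPM in double-negative cells (SD, n = 2 each), which is 5.61-fold lower with a log2 fold change of -2.49 ± 0.34 (edgeR adjusted p = 8.84e-07). Pde3a was at 17.6 ± 2.51 against 79.2 ± 8.05 CPM (-2.16 ± 0.27, edgeR adjusted p = 3.99e-08) and Tbx2 at 51.5 ± 16.2 against 130 ± 20.4 CPM (-1.36 ± 0.20, edgeR adjusted p = 5.29e-06). Plin4, a lipid droplet protein, was at 4.08 ± 0.898 against 24.5 ± 5.73 CPM (-2.58 ± 0.55), Hs3st4 at 4.7 ± 0.0138 against 25.4 ± 12.8 CPM (-2.46 ± 0.51) and Tmem215 at 6.83 ± 1.25 against 33.6 ± 12.1 CPM (-2.33 ± 0.46), with edgeR adjusted p from 0.00318 to 0.00881. Tspan8 was higher, at 76.9 ± 10.7 against 23.2 ± 2.66 CPM (1.76 ± 0.25, edgeR adjusted p = 1.96e-06), as was Tbx3os2, a transcript beside the mammary regulator Tbx3, at 20.2 ± 1.65 against 2.46 ± 1.0 CPM (2.91 ± 0.62, edgeR adjusted p = 0.00881).

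H3K4me3 was higher at 2 and lower at 18 genes (2 and 15 promoters), 1075 genes had an unadjusted p under 0.05, and DESeq2 called 21 and limma-voom 48. Tspan8hi libraries had the lower effective depth. The count was 8 and 6 without Lgr5+Tspan8hi replicate 1 and 2, 4 without Lgr5-Tspan8- replicate 2, and 48 and 49 without Lgr5-Tspan8hi replicate 1 and 2. Dcn, Pde3a and Tspan8 kept their calls under every alternative, while of the 14 named genes 9 lost theirs without Lgr5+Tspan8hi replicate 1, 10 without its replicate 2 or Lgr5-Tspan8- replicate 2, 5 without Lgr5-Tspan8- replicate 1 and 1 without Lgr5+Tspan8- replicate 2. Limma-voom ended 2 and loess offsets 1.

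H3K27me3 was lower in double-positive than in double-negative cells at Id3, an inhibitor of helix-loop-helix factors, at 1.83 ± 0.472 against 8.53 ± 1.02 CPM (SD, n = 2 each; log2 fold change -2.20 ± 0.53, edgeR adjusted p = 0.0374). Enah was at 65.4 ± 0.121 against 295 ± 38.4 CPM, 4.51-fold lower (-2.17 ± 0.16, edgeR adjusted p = 6.31e-09). Ocln was at 42.5 ± 4.36 against 129 ± 6.81 CPM (-1.61 ± 0.17, edgeR adjusted p = 3.92e-06), and the oocyte kinase gene Mos had the same log2 fold change of -1.61 ± 0.33 (edgeR adjusted p = 0.0122). It was higher at Tbx2, with 98.3 ± 9.41 against 31.2 ± 3.32 CPM (1.66 ± 0.18, edgeR adjusted p = 5.14e-06), and at Cd34, a sialomucin of progenitor and endothelial cells, with 38.0 ± 2.99 against 14.6 ± 6.45 CPM (1.41 ± 0.28, edgeR adjusted p = 0.00975). Pde3a was higher, with 328 ± 22.3 against 128 ± 9.35 CPM (1.35 ± 0.13, edgeR adjusted p = 1.06e-06), as was Serpinb2, a plasminogen activator inhibitor (1.2 ± 0.31, edgeR adjusted p = 0.0498). Members of the fixed lists with lower H3K27me3, picked out here after their values were seen, were Foxa1 of the hormone-sensing luminal cells (-0.72), Cldn7 (-1.23), Fn1 (-0.76), Pparg (-0.64), Notch1 (-1.29), Bmp2 (-0.87), Hoxa3 (-0.62), Dlx5 (-0.93) and Evx1 (-0.79), with edgeR adjusted p under the threshold. At Dcn H3K27me3 did not differ detectably (0.23, edgeR adjusted p = 0.82).

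H3K27me3 was higher at 77 and lower at 211 genes, or 73.3% lower, against 121 and 149 with loess offsets, 99 and 144 with library totals alone and 132 and 197 with offsets against reads per kb. Of the lower genes 17 were X-linked, 2950 genes had an unadjusted p under 0.05, and DESeq2 called 737 and limma-voom 699. Tspan8hi libraries had the lower effective depth. The count was 148 and 152 without Lgr5+Tspan8- replicate 1 and 2, 22 and 26 without Lgr5+Tspan8hi replicate 1 and 2, 1333 and 26 without Lgr5-Tspan8- replicate 1 and 2, and 491 and 461 without Lgr5-Tspan8hi replicate 1 and 2. Enah, Ocln, Pde3a, Ptprt and Tbx2 kept their calls under every alternative, and of the 14 named genes 9 lost theirs without Lgr5+Tspan8hi replicate 2, 7 without its replicate 1 or Lgr5-Tspan8- replicate 2, 3 without either Lgr5+Tspan8- library and 2 without Lgr5-Tspan8- replicate 1. Offsets against reads per kb ended 4, and loess offsets and RLE size factors 1 each, and DESeq2 gave no adjusted p for 5 of the genes.

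The same lists were tested in this comparison after it had given the most genes. H3K4me3 was higher at pan-luminal genes, with all 12 above 0 and a median of 0.31 (camera adjusted p = 0.00328; adjusted p = 0.305 with an estimated correlation), Elf3 at 0.72 and Cldn7 at 0.65. It was lower at fibroblast markers (8 of 12 below 0, median -0.26, or -0.05 with loess offsets, camera adjusted p = 0.00328 and 0.00772; adjusted p = 0.312 with an estimated correlation), where Dcn passed over all genes and 2 members did adjusted over the list alone. Developmental transcription factor genes were lower too (22 of 30 below 0, median -0.28, camera adjusted p = 0.00305; adjusted p = 0.305 with an estimated correlation). So were basal genes (15 of 19 below 0, median -0.18, camera adjusted p = 0.0255; adjusted p = 0.77 with an estimated correlation). These held Actg2 at -0.66, Tagln at -0.59 and Il17b at -0.53, and 1 member was lower adjusted over the list alone. H3K27me3 was higher at basal genes, with 19 of 20 above 0 and a median of 0.27 (camera adjusted p = 0.0374; adjusted p = 0.743 with an estimated correlation). It was lower at Hox genes (37 of 39 below 0, median -0.49, camera adjusted p = 1.59e-13) and at all 30 developmental genes (median -0.47, camera adjusted p = 1.96e-14), both with adjusted p = 0.604 with an estimated correlation. Of their members 19 and 18 were lower adjusted over the list alone. The lists not passing had camera adjusted p from 0.457 to 0.983 for H3K4me3 and from 0.104 to 0.977 for H3K27me3. The Tspan8hi libraries behind these groups also had the lower effective depth. With offsets against reads per kb none of these 3 H3K27me3 lists passed, the medians being 0.12 for basal genes and -0.04 for Hox and developmental genes (camera adjusted p = 0.533, 0.533 and 0.614). Olfactory receptor genes passed instead, at 0.37 (camera adjusted p = 0.00138, against 0.24 and 0.104 without those offsets). Camera calls for basal genes in H3K4me3 and H3K27me3 also ended without Lgr5-Tspan8- replicate 2 (0.866 and 0.956) or Lgr5+Tspan8hi replicate 1 (0.444 and 0.811). They ended in H3K4me3 with no filter (0.071) and in H3K27me3 with a mean of at least 5 CPM (0.0525). The H3K4me3 call at pan-luminal genes ended without Lgr5+Tspan8hi replicate 1 (0.0973).

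The marks were last compared gene by gene, to ask whether the active and the repressive mark moved in opposite directions. H3K4me3 values are read as counts around a gene start and H3K27me3 values as counts that grow with gene length. The marks may thus not have been counted over the same stretch of a gene. In the Tspan8 comparison Asb2 and Pde3a had lower H3K4me3 with higher H3K27me3, 2 genes where independent lists would share 0.00856. In the Lgr5 comparison Pde3a, Tbx2 and Ptprt did so, 3 genes against 0.0011. Between double-positive and double-negative cells 10 genes did so against 0.0726, among them Pde3a, Tbx2, Asb2, Stac, Nlgn1, Spock3, Ptprt and 2610027K06Rik, the last of which shares its promoter with Tbx2. No gene passed in any other combination of directions, but independent lists would share only 0.000367 to 0.209 genes there, so their absence shows little. Genes with higher H3K27me3 in Tspan8hi libraries had a median H3K4me3 log2 fold change of -0.51, with 20 of 20 below 0, and those higher in double-positive than in double-negative cells one of -0.57, with 61 of 66 below 0. None of 10000 random lists matched on H3K4me3 level had a median as low, in either comparison. Such lists vary only the genes drawn, not the libraries, so they do not measure the spread between samples. Both comparisons also share the double-positive and double-negative libraries. The Tspan8hi libraries had the lower effective depth in both marks. Genes with lower H3K27me3 had H3K4me3 medians of 0.05 (28 of 46 above 0) and 0.03 (105 of 190 above 0), at the 92.6 and 96.0 percentiles of such lists. Over all 16354 genes tested in both marks, which are not independent replicates, Pearson's r of the log2 fold changes was -0.011 for Tspan8, -0.003 for Lgr5 and -0.015 for double-positive against double-negative cells. Spearman's rho was -0.019, -0.011 and -0.014. Under the other settings Pearson's r ran from -0.058 to 0.01, from -0.03 to 0.008 and from -0.068 to 0.005, in the same order.

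**Figure D5:**
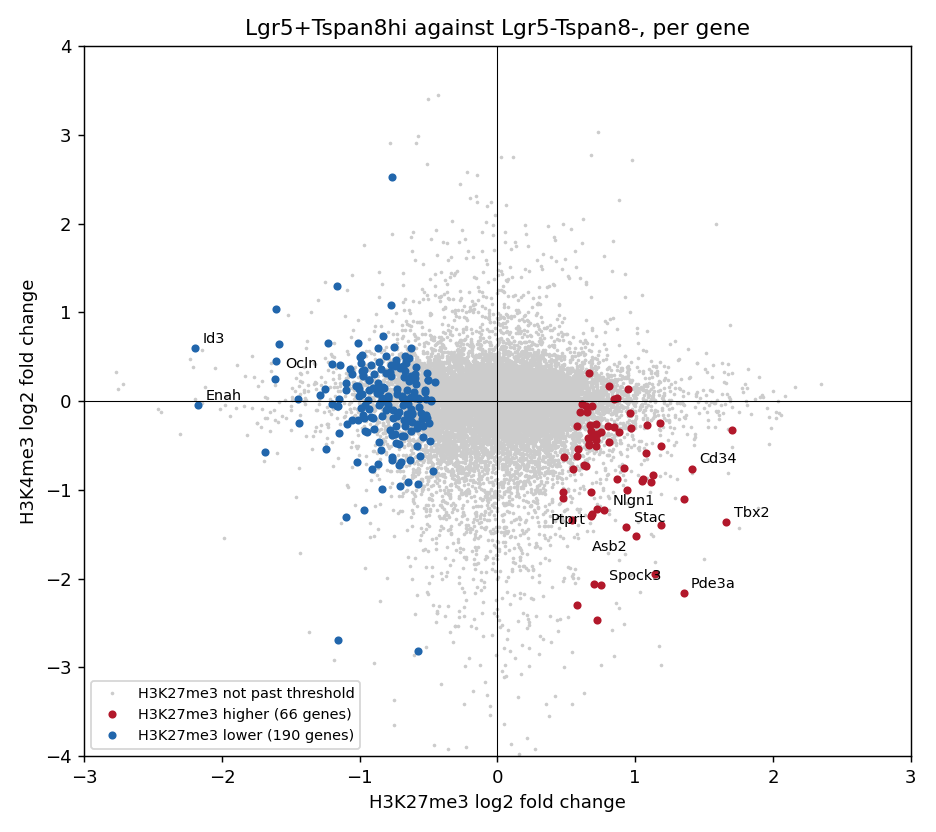
Log2 fold change of H3K27me3 (horizontal axis) against that of H3K4me3 (vertical axis), Lgr5+Tspan8hi against Lgr5-Tspan8-, for 16354 genes tested in both marks; each point is a gene, red if H3K27me3 was higher (66) and blue if it was lower (190) past the threshold, and 40 genes outside the axes are not drawn. Of the red genes 61 lie below 0 on the vertical axis, whereas the blue genes, with Enah at -0.05, spread on both sides of it.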

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

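The library comparisons and the splits of the libraries were planned, while the fits with library quality weights were chosen only after the results were seen. The sample of Lgr5-Tspan8hi replicate 1 stood apart from the other 7 samples in both marks. It had 5844 genes without a count in H3K4me3, where the next library had 3007, and 4191 in H3K27me3, where the next had 1557. Its H3K27me3 total count of 2639862 was also the lowest of that mark. Its ratio of genes without a count to those expected at its total was 4.6 in H3K4me3, within the 2.23 to 5.97 of the other libraries. In H3K27me3 that ratio was 3.31, where the next had 2.44. Its effective depth was the lowest of each mark (23.9% and 28.7%). Its H3K27me3 library had a variance over mean of 5.34 among genes with low counts (next 3.24) and a mean correlation with the other 7 libraries of 0.948 (next 0.97). In all, 12 library measures were compared in this way, and chance picks out about 1 in 20. Without this sample H3K27me3 passed at 40 genes in the Tspan8 comparison and at 491 between Lgr5+Tspan8hi and Lgr5-Tspan8- cells, where all libraries gave 74 and 288. Without replicate 2 of the same group the counts moved further in the first, to 583 and 461. The quality weights of replicates 1 and 2 were 0.73 and 0.74 for H3K4me3 and 0.67 and 0.87 for H3K27me3, the lowest of each mark.

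A pair of genes differed between Lgr5+ and Lgr5- cells in how H3K27me3 went with Tspan8, by a test of the interaction itself. The interaction was 1.88 log2 units at Grik3 and 2.10 at Rimklb. Neither call stood when Lgr5+Tspan8- replicate 1 or 2 was left out, and the highest adjusted p without 1 library was 0.104 for Grik3 and 0.636 for Rimklb in edgeR.

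The averaged comparisons were set against every split of the 8 libraries of a mark into 4 and 4, fitted with 2 groups, which made 35 splits. For H3K4me3 the Tspan8 split gave 8 genes and another split gave 11 (both Lgr5+Tspan8hi libraries with replicate 1 of Lgr5+Tspan8- and Lgr5-Tspan8hi), so that 2 of the splits, the real one included, gave as many and chance could not be excluded. The Lgr5 split gave 1 gene, 6 splits gave as many and the highest other gave 11, so chance could not be excluded. For H3K27me3 the Tspan8 split gave 19 genes and the highest other 4, so that 1 of the 35 splits, the real one, gave as many. This is the smallest share that 35 splits allow, it was not adjusted for the 6 results set against splits, and only 3 of the splits keep the replicates of each subpopulation together, of which the other 2 gave 0 genes. Splits that part the replicates leave differences between subpopulations in the residual, which can lower their counts. The real split gave more genes than any other, but chance is not excluded, either for exchange of whole subpopulations or over the 6 results. That split also separates the libraries by effective depth (42.5% ± 9.3 against 62.4% ± 3.43, SD, n = 4 each). The Lgr5 split gave 0 genes, all 35 splits gave as many, and the highest other, with 19, was the Tspan8 split. The correlation of the marks across genes was -0.0135 for the Tspan8 split and -0.0122 for the Lgr5 split, with 12 and 14 of 35 splits as negative and -0.0463 the most negative other, so chance could not be excluded for either.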

How the results depend on the processing

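The counts of genes past the threshold moved with the tool, the filter and the libraries used, most of all for H3K27me3. Where a value differed from that of edgeR with TMM, the cause was not tested, except that leaving out a library leaves fewer samples, that a lone library is then assumed to vary like the other groups, and that changing the filter changes the genes tested. Of 1740 values of the named genes under alternatives, 1409 kept direction and side of the threshold, 227 lost the threshold, 90 gained it and 14 turned direction, all 14 of them at Lgr5 or Tspan8 with values near 0 that had not passed. In simulation at these depths and numbers of libraries 1.5-fold changes were mostly missed, and depth was not varied on its own. No scaling moved the median of all genes by more than 0.1. Library quality weights, offsets against reads per kb, and lists and correlations for Lgr5+Tspan8hi against Lgr5-Tspan8- were chosen after seeing the data.

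For H3K4me3 the counts with all libraries were 9 (Tspan8), 8 (Lgr5), 0 (interaction), 1, 0 and 20 (Lgr5+Tspan8hi against Lgr5+Tspan8-, Lgr5-Tspan8hi and Lgr5-Tspan8-). DESeq2 gave 5 for Lgr5. Limma-voom gave 2 for the interaction, 4 against Lgr5+Tspan8- and 48 against Lgr5-Tspan8-, and with library quality weights 2, 4 and 62. Leaving out 1 library gave 1 to 64, 1 to 10, 0 to 7, 0 to 6, 0 to 51 and 4 to 49. For H3K27me3 the counts were 74, 9, 2, 2, 0 and 288 in the same order. DESeq2 gave 476 (Tspan8), 71 (Lgr5), 12 (interaction), 65 (against Lgr5+Tspan8-) and 737 (against Lgr5-Tspan8-). Limma-voom gave 294, 47, 2, 31 and 699, and with library quality weights 279, 46, 5, 166 and 725. No filter on low counts gave 312, 42, 15, 42 and 501, and a mean of at least 5 CPM gave 136 for Tspan8. Loess offsets gave 14 for Lgr5 and 11 against Lgr5+Tspan8-, library totals 7 against Lgr5+Tspan8-, and offsets against reads per kb 147 (Tspan8), 65 (Lgr5), 6 (interaction) and 14 (against Lgr5+Tspan8-). Leaving out 1 library gave 6 to 1091, 2 to 180, 0 to 110, 0 to 86, 0 to 323 and 22 to 1333.

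For gene lists, camera called 3 (Tspan8), 1 (Lgr5) and 4 (Lgr5+Tspan8hi against Lgr5-Tspan8-) in H3K4me3 and 4, 3 and 3 in H3K27me3. An estimated correlation gave 0 in all 6, and fry gave 0 in all but the Lgr5 comparison of H3K27me3, where it gave 3. Offsets against reads per kb gave 0, 1 and 1 in H3K27me3. Leaving out 1 library gave 1 to 4, 1 to 2 and 2 to 4 in H3K4me3 and 2 to 4, 0 to 4 and 2 to 5 in H3K27me3.

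The correlation of the marks across genes was -0.011 (jackknife SE 0.021) for Tspan8, -0.003 (0.015) for Lgr5 and -0.015 (0.017) for Lgr5+Tspan8hi against Lgr5-Tspan8-. Loess offsets gave -0.053 for Tspan8 and -0.058 for the last, offsets against reads per kb -0.058 and -0.068, a mean of at least 5 CPM -0.033, -0.03 and -0.048, and no filter 0.01 for Tspan8. Leaving out 1 library gave -0.02 to 0.008, -0.008 to 0.008 and -0.016 to 0.005.

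Values that turned direction, in log2 units, were these. H3K4me3 at Lgr5 with Tspan8 was -0.02, and ran from -0.19 to 0.13 without 1 library (0.12 without Lgr5+Tspan8hi replicate 1, 0.13 without Lgr5-Tspan8- replicate 2 and 0.01 without Lgr5-Tspan8hi replicate 1). H3K4me3 at Tspan8 with Lgr5 was 0.07, and ran from -0.05 (without Lgr5+Tspan8- replicate 1) to 0.15, with 0.00 without Lgr5+Tspan8hi replicate 2. H3K27me3 at Lgr5 with Tspan8 was 0.01, and -0.01 with limma-voom, -0.02 with quality weights, -0.09 with offsets against reads per kb and 0.00 with a mean of at least 5 CPM or no filter. Without 1 library it ran from -0.23 to 0.19, and was -0.01 without Lgr5+Tspan8- replicate 2, -0.23 without Lgr5+Tspan8hi replicate 1, -0.08 without Lgr5-Tspan8- replicate 2 and -0.04 without Lgr5-Tspan8hi replicate 1.

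Replicate numbers are shared between groups in the labels, which do not say whether same-numbered samples were handled together. The main fits did not pair them, and a pairing stays open. Over the 6 pairs of groups, deviations of same-numbered libraries correlated at -0.03 to 0.14 for H3K4me3 (1 pair above 0.1) and -0.01 to 0.12 for H3K27me3 (2 pairs above 0.1). With the number as a replicate block the counts of genes were 13, 8, 0, 1, 0 and 29 for H3K4me3 and 678, 80, 13, 168, 0 and 955 for H3K27me3. The counts of lists were 3, 1, 4 and 4, 3, 3, and the correlations -0.01, -0.006 and -0.015.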

Other observations

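The tests against offsets by reads per kb of gene, the test of the number of active X chromosomes and the list tests between Lgr5+Tspan8hi and Lgr5-Tspan8- cells were chosen only after the results were seen. H3K27me3 over X-linked genes was lower in Tspan8hi than in Tspan8- libraries. Of 1021 X-linked genes tested, 922 (90.3%) had a log2 fold change below 0, with a median of -0.27, against 44.9% of autosomal genes, and the medians of the 19 autosomes lay from 0.01 to 0.08. The X-linked median was -0.22 to -0.28 under the other library scalings and -0.13 with offsets against reads per kb. X-linked H3K4me3 had a median of 0.002 ± 0.015 (SE) over 595 genes, which was 0.05 with loess offsets and -0.01 with library totals. In Lgr5+ against Lgr5- libraries the X-linked H3K27me3 median was -0.08, which was -0.01 with offsets against reads per kb. The X-linked deviations of the libraries did not differ detectably with Lgr5 (exact two-sided permutation p = 0.914, n = 4 each).

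Gene groups were also tested for change in either direction. With fry's mixed test, which asks whether members change at all, 1 list passed for H3K27me3 in the Tspan8 comparison, the adipocyte list with Pparg (adjusted p = 0.0435), 2 in the Lgr5 comparison and 8 between Lgr5+Tspan8hi and Lgr5-Tspan8- cells. With an estimated correlation camera called 0 lists in each of these comparisons (adjusted p = 0.705 for the adipocyte list), and the Tspan8hi libraries had the lower effective depth. In fry's directional test, hormone-sensing luminal genes (median log2 fold change -0.09) and Notch pathway genes (-0.16) were lower in H3K27me3 with Lgr5, with 10 of 13 and 7 of 12 members below 0. Olfactory receptor genes (0.12) were higher, with 377 of 640 above 0 (fry adjusted p = 0.0416 for each of the 3 lists). Camera did not call the first pair, and with an estimated correlation its adjusted p was 0.603 for both and 0.0841 for olfactory receptor genes.

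The first pattern weighed is the lower X-linked H3K27me3 in Tspan8hi libraries. X-linked genes are densely marked. Lists of autosomal genes matched on reads per kb, 10000 in all, had a median of -0.12 and a lowest value of -0.17. The observed -0.27 lay below both. In these libraries weaker enrichment at densely marked genes could thus account for part of the difference but not all of it. The lists vary only the genes drawn, not the libraries. Fewer copies of the active X chromosome would lower both marks, and H3K4me3 at 0.002 ± 0.015 argues against that, but not against fewer copies of the inactive X, which carries dense H3K27me3 and little H3K4me3. Deviations of the libraries from autosomal genes of like density were -0.0742 ± 0.0327 against 0.0742 ± 0.0744 (SD, n = 4 each; exact two-sided permutation p = 0.0286, the smallest that 70 arrangements allow), but the X was singled out from the same libraries and p is 0.0571 adjusted for the 2 averaged comparisons, so a chance order stays open. In replicates 1 and 2 the deviations were -0.06 and -0.04 in Lgr5+Tspan8hi and -0.11 and -0.09 in Lgr5-Tspan8hi cells. They were 0.02 and 0.09 in Lgr5+Tspan8- and 0.01 and 0.17 in Lgr5-Tspan8- cells, so the Tspan8- side rested mainly on its replicate 2 libraries. Library complexity, which parts the libraries in the same way, stays open, as do the inactive X and a difference in X-linked silencing between the cells, which were not tested.

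The second pattern is the lower H3K4me3 at Dcn in Lgr5+ libraries. Fibroblasts in the Lgr5- sorts would bring the marks of their other genes. The other 11 fibroblast markers had a median of -0.06 (SE 0.10, range -0.62 to 0.25). Dcn had -1.52, with -0.76 as its midpoint. These values argue against fibroblasts that would move all markers alike. Markers already marked in basal cells would move less than Dcn, and the markers were not matched on level, so a few fibroblasts stay open. A single extreme library is argued against by the highest edgeR adjusted p of 0.013, reached without Lgr5+Tspan8hi replicate 2, the lowest being 9.35e-07. With Tspan8 and between double-positive and double-negative cells camera called the fibroblast list lower, with 9 of 12 and 8 of 12 members below 0. Neither call held with an estimated correlation (camera adjusted p = 0.565 and 0.312), and fibroblasts there stay open too. A difference between Lgr5+ and Lgr5- basal cells at Dcn itself may remain as a hypothesis.

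The third pattern is the excess of lower over higher H3K27me3 in double-positive against double-negative cells, 73.3% of the genes past the threshold. Leaving out any of the 4 libraries compared left at least 72.7% of the called genes lower. Most of these fits kept few of the calls, and each left 1 library in a group, so an excess driven by a single library stays open. Loess offsets, which remove a trend with mean abundance between libraries, left 55.2%. Higher genes rose from 77 to 121 and lower ones fell from 211 to 149. The median log2 fold change of the 211 genes stayed near its first value (-0.78, quartiles -0.95 and -0.64, against -0.71, quartiles -0.90 and -0.56). The share of 55.2% lies within the 40% to 60% taken as even, so a trend with abundance could account for much of the excess in calls. The 211 genes were picked as lower in these same data, so the fold they kept does not test that explanation. Loess offsets left the trend with density, at -0.33 in the densest decile against -0.37 without them. They therefore do not test a difference in enrichment that follows density. Offsets against reads per kb left 59.9% (132 and 197), mainly because more genes were called higher, but took the 211 genes to -0.57 (quartiles -0.84 and -0.38) and the 87 that lost the call from -0.71 to -0.36, so weaker enrichment at densely marked genes may have a part in the excess and stays open. Hox and developmental genes, with medians of 9.87 and 8.59 CPM per kb against 0.651 over all genes, fall among the densest genes, and their lower values (-0.49 and -0.47) were each -0.04 with those offsets, so whether the cells differ in the mark at those genes stays open too.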
